A study of Locusta migratoria with 12 samples.

How the data were processed

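Small RNA was sequenced from fat body of adult female locusts at 4 ages, 0, 2, 4 and 6 days after eclosion, with 3 libraries per age. RNA was extracted with TRIzol and libraries followed a standard Illumina protocol, per the labels' protocols. The values are raw counts per mature miRNA name, deposited by the authors in a table of 26711 names under 115 species prefixes. The aligner, the mismatches allowed, the miRNA release and the genome are not given in the sources used here. The groups and replicate numbers come from the sample titles, and each of the 12 columns was matched to a sample through its description. There were 0 columns of other samples.

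Of the names, 5500 held counts, in 884 distinct profiles, and 14 names were of the locust. Rows of the same miRNA from different species often held the same counts, from which it was inferred that reads were counted again under each matching name, so rows are not independent. Rows with at least 120 counts over the 12 libraries (1513 rows) were therefore joined into groups. Rows of the same miRNA number were joined where they agreed within 25% plus 5 counts in every library, and rows of other numbers within 5% plus 3 counts, which left 154 profiles. A profile that was a constant share of a more abundant group of the same number, arm and paralogue letter was then joined to it. The share had to hold within a factor of 1.5 or 2.5 counting SDs, with 1 library allowed outside. This left 99 groups, 83 with an arthropod name and 16 without. Each group is named after a locust row where it has one, otherwise after another insect or arthropod, and its counts are those of its most abundant row. Paralogues that share reads may still be split or joined, so their values are uncertain. The design had assumed the rows as they stand; the joining was decided after the repeated counting was seen, and a fit of all rows is among the alternatives.

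The main test was edgeR 4.0.16 (R 4.3.3, limma 3.58.1) with TMM factors, filterByExpr (minimum count 10), glmQLFit and glmQLFTest on all 12 libraries with age as a factor, which tested 91 groups. A miRNA is called changed at a Benjamini-Hochberg adjusted p under 0.05. The standard error of a log2 change is its size divided by the square root of the F value. Levels are normalised CPM. The 5 planned comparisons were each later age with day 0 and the steps between consecutive ages, beside a test over the 4 ages. The comparison of day 6 with day 2 and a fit without day 0 were added after seeing the data, as was reading each count without day 0 replicate 1. The unplanned choices apart, groups, tests and lists were fixed before the data were examined.

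Named miRNAs were chosen by a fixed rule. For each comparison with day 0 they were the 10 largest rises and 10 largest falls among called miRNAs with at least 10 CPM on average and no overlap between the libraries of the 2 ages; chance gives no overlap in 10% of cases with 3 against 3. For each step the number was 5. Variants of a mature miRNA counted once, by the most abundant, which set aside the minor forms of miR-8-3p, miR-100 and miR-125, a form of miR-750 named only in a limpet and the vertebrate form of miR-1. The 10 most abundant miRNAs and the members of each list with the lowest p were added. Other miRNAs named were chosen after their values were seen. Of 17 lists, 14 had at least 2 measured members and were tested with fry, adjusted over the lists of a comparison, with camera and an estimated correlation, and with total counts, as alternatives. fry's p tests whether a list moves, on balance, in a single direction and does not compare it with other miRNAs. The miR-12/283/304 cluster and the miR-92 family had 1 measured member each and the ovary and early embryo list 0.

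Counting error was small for abundant miRNAs, since the smallest library held 383406 counts. The test was tried on simulated counts for day 6 against day 0, with 30 of 91 groups changed in each of 20 runs. It recovered 11% of 2-fold, 71.5% of 4-fold and 95% of 8-fold changes, with 0 wrong signs and a false share of 3.8%. The simulated spread was the trend with abundance estimated from all 12 libraries, day 0 replicate 1 included. Each miRNA was drawn independently around 1 mean apart from the planted changes. No miRNA had a spread of its own and no library stood apart as a whole, unlike in the data. In such counts, changes near 2-fold were mostly missed with 3 libraries per age. The recovery and the false share need not hold for the real libraries. Recovery without that library was not simulated. The alternatives were RLE factors, total counts, no filter, DESeq2 1.42.0, limma-voom, blocks by replicate number, summed names, only the libraries compared, each library left out, leaving out the most abundant miRNA, all rows, the first joining step alone and arthropod names alone. Rows were joined with Python 3.11.15, pandas 2.3.3 and NumPy 2.4.6, exact tests used SciPy 1.17.1 and figures matplotlib 3.10.9.

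For day 0 replicate 1, the test of a mixture with another insect's RNA replaced an earlier one after its result was seen. The earlier test used ratios of conserved miRNAs to miR-8-3p and had come out against a mixture as the only cause. It took those rows to count locust reads alone and paired some different paralogues. The test that replaced it still takes miR-8-3p to count locust reads alone.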

Results

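Small RNA libraries were made from the fat body, the insect organ that stores nutrients and produces yolk proteins, of adult female migratory locusts (Locusta migratoria). The females were sampled at 0, 2, 4 and 6 days after adult eclosion, the moult to the adult, with 3 libraries at each age. The rows were joined into 99 groups, called miRNAs below, though some are forms of the same miRNA. Their counts came to between 383406 (day 0 replicate 1) and 2299299 (day 2 replicate 1) per library. miR-8-3p, a miRNA tied to insulin signalling and growth in flies, was the most abundant, with a mean share of 45.35% of a library's counts over the 12 libraries. By mean normalised level it was followed by miR-276-3p, with a mean share of 11.25%, bantam-3p with 6.7%, miR-184-3p with 5.6%, miR-14-3p with 2.77%, miR-275-3p with 2.94%, miR-9c-5p with 2.54%, miR-125-5p with 2.62%, miR-100-5p with 2.58% and miR-8-5p with 2.11%. Over the 11 libraries other than day 0 replicate 1, miR-275-3p, miR-125-5p and miR-100-5p held 2.12%, 1.68% and 1.59%, miR-9c-5p and miR-8-5p ranked above miR-275-3p, and miR-306 with 2.12% took the place of miR-100-5p among the 10 most abundant. The labels call the 3 libraries of an age separate samples and do not say whether they came from separate animals, so p-values measure the spread between these libraries, which may be technical.

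Day 0 replicate 1 stood apart from the other 11 libraries. Its median correlation with them, across miRNAs on the log2 scale, was 0.85, against 0.93 to 0.98 for the others. miR-8-3p took 8.3% of its counts, against 36% and 27.1% in the other day 0 libraries. It held 1896 counts of miRNAs named only in Lepidoptera (moths and butterflies), against at most 10 in any other library. Every comparison with day 0 rests in part on this library, so each total of changed miRNAs is given with and without it.

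**Figure D1:**
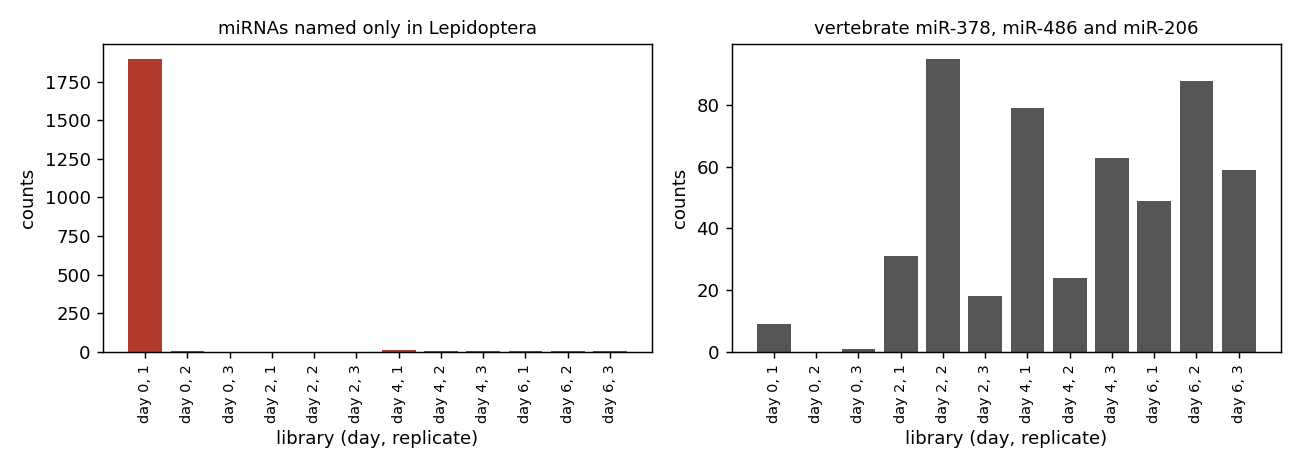
Bars show raw counts per library of miRNAs named only in Lepidoptera (left) and of 3 miRNAs named only in vertebrates (right), for 12 libraries ordered by day and replicate. The left bar of day 0 replicate 1 stands at 1896 and no other library passes 10; on the right the 3 day 0 libraries hold 10 counts together and the 9 later ones 506.

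Over the 4 ages, 25 of the 91 miRNAs tested changed, with edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05. miR-31-5p had the smallest p (adjusted p = 0.000125), ahead of miR-263a-5p (adjusted p = 0.000785). The test called 33 miRNAs without day 0 replicate 1, and 20 of them were among the 25.

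**Figure D2:**
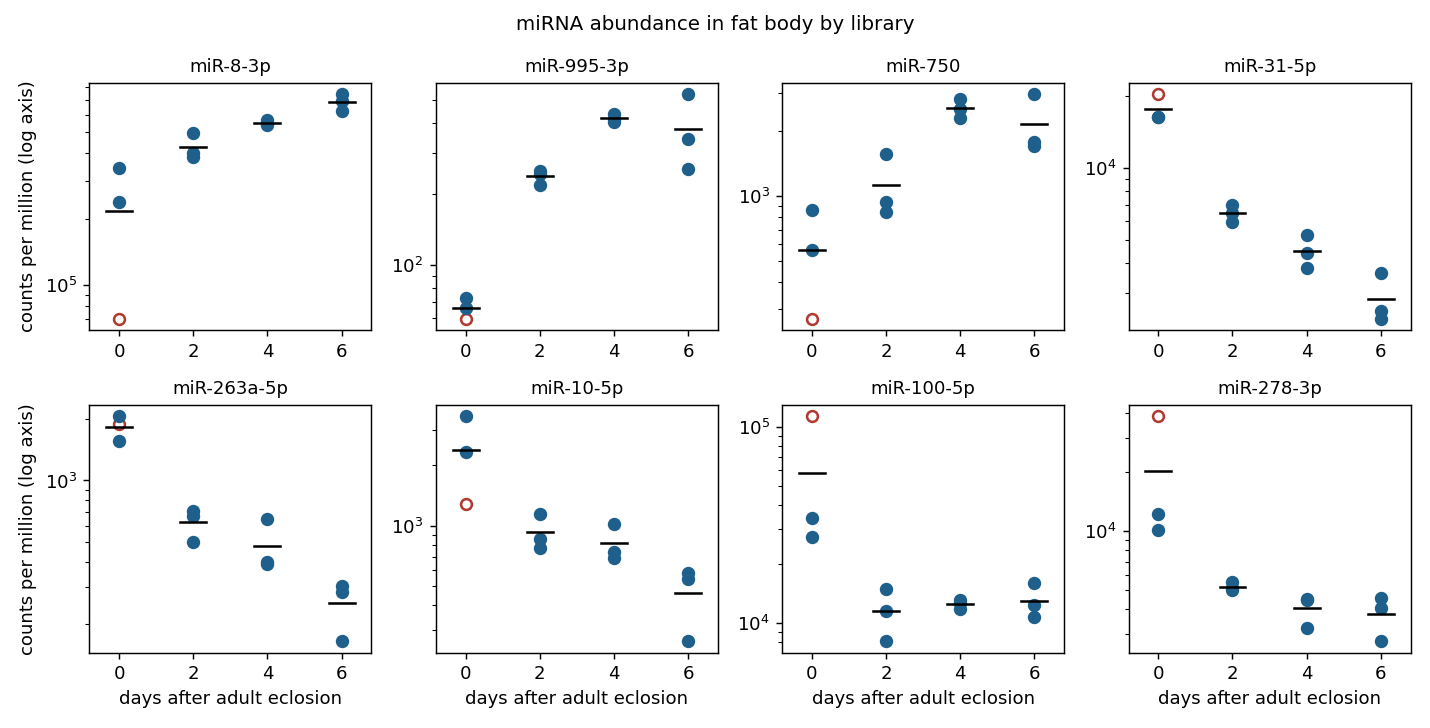
Points show normalised CPM (log axis) of 8 miRNAs in each of the 12 libraries against days after adult eclosion, and short lines the mean of the 3 libraries of a day. The open red point is day 0 replicate 1. miR-995-3p averaged 66.1 at day 0 and 420 at day 4, and miR-31-5p fell from a mean of 17740 at day 0 to 2818 at day 6.

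The comparison of day 2 with day 0 asked what changed in the days just after eclosion. miR-31-5p fell by 1.45 on the log2 scale (SE 0.26, 3 libraries per age), from 17740 ± 2335 to 6473 ± 533 CPM (counts scaled to a common library size; mean ± SD, n = 3). miR-263a-5p and miR-263b-5p, related miRNAs with a role in sensory organ survival in flies, fell by 1.55 (SE 0.35) and 1.35 (SE 0.37). miR-10-5p, encoded within the Hox gene cluster, fell by 1.36 (SE 0.42), and miR-92a fell by 2.37 (SE 0.64). miR-100-5p and miR-125-5p, which share a transcript with let-7 in many insects, fell by 2.33 (SE 0.48) and 1.98 (SE 0.47), and miR-278-3p, linked to energy balance in flies, fell by 1.96 (SE 0.46). miR-995-3p rose by 1.84 (SE 0.35), from 66.1 ± 6.89 to 238 ± 17.3 CPM, and miR-8-5p rose by 0.81 (SE 0.25). miR-9341, named only in a vertebrate, rose by 2.34 (SE 0.62).

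In all, 4 miRNAs rose and 11 fell between day 0 and day 2. The rises include miR-9341 and the vertebrate form of miR-1, which have no arthropod name. With day 0 replicate 1 left out, 8 rose and 12 fell, and all 4 of the risen and 10 of the fallen miRNAs were called again. The falls of miR-100-5p, miR-125-5p, miR-278-3p and miR-92a were then smaller, at -1.42, -1.06, -1.10 and -1.28, while miR-31-5p stood at -1.34 and miR-263a-5p at -1.53. miR-2765-5p was called only without that library, with a log2 change of 2.44 (adjusted p = 0.00529) against 1.24 with it. Other single libraries moved the counts too: there were 8 higher and 20 lower without day 0 replicate 2, 4 lower without day 2 replicate 1, 1 higher and 7 lower without day 2 replicate 2, and 2 higher and 7 lower without day 2 replicate 3. Counts near those of the full fit are not given, here and at the later ages.

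Of the 15 miRNAs called at day 2, 5 were called whichever single library was left out, among them miR-31-5p (log2 change -1.56 to -1.34), miR-100-5p (-2.70 to -1.42) and miR-995-3p (1.77 to 1.93). The calls of miR-8-5p and miR-10-5p each ended in 9 of these 12 fits, with values of 0.56 to 0.93 and -1.66 to -0.96 over the 12 fits. Leaving out day 2 replicate 1 ended the calls of miR-125-5p (-1.86), miR-278-3p (-2.0), miR-263a-5p (-1.41), miR-263b-5p (-1.10) and miR-92a (-2.28). The call of miR-278-3p also ended without day 2 replicate 2 (-1.93), that of miR-263b-5p without day 2 replicate 3 (-1.41), and that of miR-92a without either (-2.63 and -2.26). The call of miR-9341 ended without day 0 replicate 3 (2.22), day 2 replicate 2 (2.22) or day 2 replicate 3 (2.11).

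The comparison of day 4 with day 0 asked the same of a later age. miR-995-3p rose by 2.66 on the log2 scale (SE 0.36) to 420 ± 16.9 CPM. miR-750 rose by 2.17 (SE 0.44) and miR-33-5p, which lies within a gene of a lipid regulator in flies and mammals, rose by 2.56 (SE 0.71). miR-8-3p rose by 1.34 (SE 0.43), miR-8-5p by 1.22 (SE 0.25) and miR-252a-3p by 1.27 (SE 0.36). A minor form of miR-8-3p (dme-miR-8-3p), singled out after its values were seen, fell by 4.66 (SE 1.07) at day 4, with log2 changes of -5.15 at day 2 and -4.53 at day 6. It stood at 2096 CPM in day 0 replicate 1, at 117 and 92.8 in the other day 0 libraries and at 30.04 ± 5.19 at day 4, and its changes at days 2, 4 and 6 were -2.27, -1.79 and -1.67 without day 0 replicate 1. miR-31-5p fell by 1.98 (SE 0.27), miR-263a-5p by 1.93 (SE 0.35) and miR-263b-5p by 1.64 (SE 0.37).

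miR-1-3p, an abundant muscle miRNA, fell by 4.08 on the log2 scale (SE 0.97) at day 4, but its 3 day 0 libraries ranged from 182 to 3347 CPM. miR-92a fell by 3.22 (SE 0.66), miR-278-3p by 2.32 (SE 0.46), miR-100-5p by 2.20 (SE 0.48) and miR-125-5p by 1.96 (SE 0.47). Smaller falls were those of miR-184-3p, by 1.28 (SE 0.29), and let-7, by 0.82 (SE 0.25). miR-2796-3p and miR-193 fell by 2.74 and 2.70. Both calls ended without day 0 replicate 1, where the log2 changes were -0.33 (adjusted p = 0.558) and -1.03 (adjusted p = 0.118). miR-9341 rose by 2.25 (SE 0.62).

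Between day 0 and day 4, 9 miRNAs rose and 18 fell. Groups with no arthropod name were among them. miR-9341, the vertebrate form of miR-1 and the limpet form of miR-750 rose, and miR-99b-5p fell. Leaving out day 0 replicate 1, 14 rose and 17 fell, and 9 of the risen and 14 of the fallen were called again. miR-100-5p, miR-125-5p, miR-278-3p and miR-92a then changed by -1.29, -1.03, -1.46 and -2.12. There were 5 higher without day 0 replicate 3, 3 higher and 11 lower without day 4 replicate 1, and 5 higher and 11 lower without day 4 replicate 3.

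At day 4, 14 of the 27 calls held whichever single library was left out, among them those of miR-31-5p, miR-995-3p, miR-750, miR-8-5p, miR-263a-5p, miR-263b-5p and miR-184-3p. The fall of miR-1-3p was also called in each of these fits, at -3.26 without day 0 replicate 2. The call of miR-8-3p ended without day 0 replicate 3 (1.43), day 2 replicate 3 (1.31) or day 4 replicate 1 (1.31), 2 (1.34) or 3 (1.32). That of miR-252a-3p ended without day 0 replicate 3 (1.24) or day 4 replicate 1 (1.20), 2 (1.24) or 3 (1.31), and that of let-7 without day 4 replicate 1 (-0.80), 2 (-0.83) or 3 (-0.88). The call of miR-33-5p ended without day 4 replicate 1 (2.37), and that of miR-9341 without day 0 replicate 2 (1.84), day 0 replicate 3 (2.14) or day 4 replicate 1 (1.87). Those of miR-2796-3p and miR-193 ended without any 1 of the 3 day 4 libraries, with values of -2.89 to -2.49 and -2.84 to -2.53.

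By day 6, miR-31-5p had fallen by 2.65 on the log2 scale (SE 0.27, adjusted p = 4.45e-05), to 2818 ± 701 CPM. miR-263a-5p fell by 2.86 (SE 0.37), miR-263b-5p by 2.69 (SE 0.38), miR-10-3p by 2.54 (SE 0.42) and miR-10-5p by 2.37 (SE 0.44). miR-9a-5p fell by 1.78 (SE 0.56). miR-8-3p rose by 1.66 (SE 0.43), from 217500 ± 138000 to 686900 ± 60340 CPM, and its log2 change was 1.24 (SE 0.17) when day 0 replicate 1 was left out. miR-995-3p rose by 2.5 (SE 0.36), miR-750 by 1.93 (SE 0.43), miR-8-5p by 1.11 (SE 0.25), miR-252a-3p by 0.96 (SE 0.36) and miR-9c-5p by 0.82 (SE 0.27).

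miR-92a fell by 3.52 (SE 0.68), miR-278-3p by 2.42 (SE 0.46) and miR-193 by 3.28 (SE 0.88) at day 6. These values were -2.43, -1.56 and -1.60 without day 0 replicate 1. miR-2796-3p and miR-998-3p fell by 3.24 and 2.28, and both calls ended without that library, with log2 changes of -0.84 (adjusted p = 0.112) and -0.57 (adjusted p = 0.212). miR-252-5p was not called with all 12 libraries, at -0.82, and without day 0 replicate 1 it was called in the other direction, at 0.82 (adjusted p = 0.00161). miR-378, named only in vertebrates, was called as higher in the fit of all 12 libraries, from 7, 0 and 1 counts in the day 0 libraries to 40, 62 and 44 at day 6.

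Between day 0 and day 6, 12 miRNAs rose and 23 fell. Groups with no arthropod name were among them. miR-378, miR-9341, the vertebrate form of miR-1, miR-33a and the limpet form of miR-750 rose, and miR-99b-5p fell. miR-33a and the limpet form stand beside miR-33-5p and miR-750, which were called too. In the fit lacking day 0 replicate 1, 15 rose and 23 fell, and 12 of the risen and 19 of the fallen were called again. With total counts in place of TMM factors, 6 rose and 25 fell, and the median log2 change of all miRNAs was -0.06 in place of 0.32. There were 7 higher without day 0 replicate 3, 7 higher without day 6 replicate 1, 6 higher and 14 lower without day 6 replicate 2, and 15 lower without day 6 replicate 3.

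At day 6, 20 of the 35 calls held whichever single library was left out, among them those of miR-31-5p, miR-263a-5p, miR-263b-5p, miR-10-5p, miR-10-3p, miR-995-3p, miR-750, miR-8-3p and miR-8-5p. The call of miR-252a-3p ended in 10 of these 12 fits, with values of 0.78 to 1.16 over the 12 fits, and that of miR-9c-5p in 7, with values of 0.58 to 1.01. The call of miR-9a-5p ended without day 0 replicate 2 (-1.58), day 0 replicate 3 (-1.44), day 6 replicate 2 (-1.62) or day 6 replicate 3 (-1.57). That of miR-193 ended without day 6 replicate 2 (-3.12) or 3 (-3.02), that of miR-2796-3p without the same libraries (-3.25 and -2.97), and that of miR-998-3p without day 6 replicate 1 (-2.35), 2 (-2.27) or 3 (-2.23). The call of miR-378 ended in 5 of the 12 fits.

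Groups of miRNAs listed before the data were examined were compared with day 0 as well. The let-7 complex (let-7, miR-100 and miR-125) had 5 of its 6 measured members fallen at day 4 and at day 6, and 5 adjusted over the list alone at each age. They were let-7 and the major and minor forms of miR-100 and miR-125, and 4 were called at each age without day 0 replicate 1. Its rotation test (fry) at day 6 gave an adjusted p of 0.0432, with a median log2 change of -2.12 that was -1.02 without day 0 replicate 1. In camera it gave an adjusted p = 0.67 with an estimated correlation. Among the chitin and moulting miRNAs of locusts, 3 of 6 fell at day 4 and at day 6, also 3 adjusted over the list alone, and these were miR-184-3p, miR-263a-5p and miR-263b-5p. Their test gave an adjusted p of 0.0195 at day 4 and 0.00192 at day 6, and camera gave an adjusted p = 0.764 at day 4 and an adjusted p = 0.67 at day 6 with an estimated correlation. The Hox cluster miRNAs had 2 of 3 members fallen at day 6, the arms of miR-10, and 2 adjusted over the list alone, with an adjusted p of 0.0104 in fry and adjusted p = 0.67 with an estimated correlation.

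The miRNAs reported to target Kr-h1, a gene of the juvenile hormone response, had 2 of 4 members fallen at day 6, let-7 and miR-278-3p, and 3 adjusted over the list alone (adjusted p = 0.0481 in fry, and adjusted p = 0.67 with an estimated correlation). The metabolic miRNAs had 4 members risen (miR-8-3p, miR-8-5p, miR-33-5p and miR-33a) and 2 fallen (miR-278-3p and the minor form of miR-8-3p) of 10, with 7 adjusted over the list alone. Their adjusted p was 0.0499 in fry, and adjusted p = 0.67 with an estimated correlation. In day 6 replicate 3, miR-33-5p stood at 65.6 CPM and miR-33a at 4.1, under or within their day 0 ranges of 74.5 to 109 and 0 to 9.0, and the call of miR-33a ended without day 0 replicate 2 (2.39), day 6 replicate 1 (1.92) or day 6 replicate 2 (2.65), while its value was 3.68 without day 0 replicate 3. Of the 5 measured members of the mosquito reproduction list, 2 rose and 1 fell, with 3 adjusted over the list alone, and all 3 were forms of miR-8: miR-8-3p and miR-8-5p rose and the minor form of miR-8-3p fell. Its adjusted p was 0.0499 in fry, and adjusted p = 0.68 with an estimated correlation. Its other members, miR-275-3p (-1.06, and 0.21 without day 0 replicate 1) and miR-277-3p (0.69), were not called, and the list's median and mean log2 changes, 0.69 and -0.43, differed in sign. The cluster of miR-2, miR-13 and miR-71 passed the test at day 6 with 0 of 7 members called, 0 adjusted over the list alone, and a median of 0.44 against 0.32 for all miRNAs (adjusted p = 0.0259 in fry, and adjusted p = 0.67 with an estimated correlation). With total counts in place of TMM factors its median was 0.08, against -0.06 for all miRNAs, and it was not called (adjusted p = 0.674 in fry). The metabolic and mosquito reproduction lists were then not called either (adjusted p = 0.674 and 0.53).

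The test called 4 lists at day 2, 5 at day 4 and 7 at day 6 when day 0 replicate 1 was left out, against 0, 1 and 7 with it. In camera without that library, no list was called, with the lowest adjusted p = 0.578 at day 2, 0.803 at day 4 and 0.716 at day 6 with an estimated correlation. In fry without it, the metabolic list gave an adjusted p of 0.304 at day 6 and was no longer called. The hormone-responsive miRNAs, of which 3 rose and 7 fell of 16 at day 6, with 10 adjusted over the list alone, gave an adjusted p of 0.0933, and 0.0306 without that library, where 4 rose and 6 fell. Camera gave this list an adjusted p = 0.67 with an estimated correlation, and fry an adjusted p of 0.0346 with total counts. The cluster of miR-9, miR-79 and miR-306 had 1 risen and 2 fallen of 7 at day 6, with 3 adjusted over the list alone (adjusted p = 0.801). Its members were 2 risen and 2 fallen without day 0 replicate 1. The cluster of miR-277, miR-34 and miR-317 and that of miR-275 and miR-305 had 0 members called at day 6, 0 adjusted over the list alone, with an adjusted p of 0.45 for each.

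Markers of other tissues were listed too. Of the 3 muscle rows, miR-1-3p fell, miR-133-3p was not called, and the vertebrate form of miR-1 rose at day 6 (2 adjusted over the list alone; adjusted p = 0.45). The day 6 call of miR-1-3p ended without day 0 replicate 2 (log2 change -1.86), day 0 replicate 3 (-2.68) or day 6 replicate 1 (-2.20), 2 (-3.21) or 3 (-2.77). The nervous system list and the gut and Malpighian tubule list each had 0 of 3 members called at day 6, 0 adjusted over the list alone (adjusted p = 0.948 and 0.72). The gut miRNA miR-281-3p ranged from 57.8 to 1015 CPM within day 0.

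The steps between consecutive ages asked when the change took place. With edgeR on all 12 libraries, 0 of 91 miRNAs passed the threshold between day 2 and day 4, with 5 at an unadjusted p under 0.05. DESeq2 called 1, limma-voom 0, and edgeR on only the 6 libraries compared 4. Between day 4 and day 6 edgeR, DESeq2 and limma-voom each called 0, with 6 at an unadjusted p under 0.05 in edgeR. Without day 0 replicate 1, which is in neither arm but adds to the shared spread, miR-184-3p was called as lower at day 4 than at day 2 (log2 change -0.66) and so was miR-315-5p (-3.59). The 3 values of miR-315-5p at day 2 were 129, 70.8 and 533 CPM, and leaving out day 2 replicate 2 also gave 1 lower miRNA.

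Day 6 was compared with day 2 after the day 0 libraries had been seen to differ. miR-31-5p changed by -1.20 (SE 0.26), miR-263a-5p by -1.31 (SE 0.35), miR-9a-5p by -1.59 (SE 0.56) and miR-8-3p by 0.69 (SE 0.42) on the log2 scale. With all 12 libraries and no replicate block, edgeR called 0 miRNAs, with 14 at an unadjusted p under 0.05. DESeq2 called 4 as lower and limma-voom 0. On only the 6 libraries compared, edgeR called 4. When day 0 replicate 1 was left out, 3 rose (miR-8-3p, miR-252-5p and miR-34-5p) and 6 fell (miR-31-5p, miR-263a-5p, miR-263b-5p, miR-9a-5p, miR-10-3p and miR-184-3p), and 1 was lower without day 6 replicate 1. These miRNAs were named after their values were seen. A fit of the days 2, 4 and 6 alone called 2 as higher and 6 as lower.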

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

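All tests in this part were chosen after the results they bear on were seen. The one on depth was also rerun on another scale after its first result. No library was tested as an outlier within its age, since that test was kept to groups of at least 4 libraries.

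miRNAs named only in Lepidoptera, data outside the comparisons, gave 1896 counts in day 0 replicate 1 (598 of miR-2763, 547 of miR-3338 and 399 of miR-2766) and at most 10 in any other library, which is consistent with reads of a lepidopteran insect in that library. Lower depth is argued against, since the other 11 libraries, thinned to the same total, kept a median correlation of at least 0.93, against 0.83 for day 0 replicate 1. Whether such reads are the only cause cannot be told apart from a further difference. miR-8-3p stood at 0.26 of its level in the other day 0 libraries. Of 77 miRNAs, 2 lay under 0.066 (miR-279-3p and miR-81a, with 3 and 4 counts). A plain mixture would not give such values if miR-8-3p counted locust reads alone. That is not known, so the test cannot decide, and 2 are too few to exclude a mixture. Among abundant miRNAs, miR-14-3p and bantam-3p, with 1515 and 7068 counts, also lay under the miR-8-3p ratio, at 0.127 and 0.18. If the locust part of a mixture matched the other day 0 libraries, its share could not exceed such ratios. The share of locust reads in this library is not known and may be small. The other insect's profile is not known, so miRNAs that were high in this library may count its reads to an unknown extent. Of the 77, 12 stood above 4 times their level in the other day 0 libraries. The minor form of miR-8-3p (21.9) and miR-2796-3p (15.2) were highest. miR-998-3p (8.9), miR-252-5p (8.0) and miR-92a (4.9) were also above miR-125-5p (4.01), miR-100-5p (3.96) and miR-278-3p (3.76). A median log2 shift of 1.86 in the ratio of 8 conserved miRNAs to miR-8-3p decides nothing. No biological explanation was tested.

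Counts under vertebrate names were the other signal. miR-378, miR-486 and miR-206, known from vertebrate muscle and blood, gave 506 counts in the 9 later libraries, 18 to 95 in each, and 10 in the 3 day 0 libraries. In CPM, day 0 averaged 8.0 and the later days 54.3 (exact permutation test, two-sided p = 0.0364, 3 against 9 libraries), but day 0 replicate 1 held 23.5, above the lowest later library with 13.5. Most of these counts were of miR-378, which was itself among the miRNAs compared and was called as higher at day 6. The permutation test thus largely repeats that rise and is not separate support for it.

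miRNAs called at day 4 against day 0 may reflect handling of the day 0 libraries apart from the rest, for which the labels give no batch. Vertebrate reads in the later libraries are argued against for the 18 falls. At least 88.3% of the counts of each day 4 library were of miRNA numbers with no vertebrate name. The rest could lower other miRNAs by dilution to -0.18 on the log2 scale at most, against -4.96 to -1.06 for the falls with total counts. Such reads are also argued against for 6 of the 9 rises, whose numbers have no vertebrate name and which were also called without day 0 replicate 1. In day 0 replicates 1, 2 and 3 the share of counts under numbers with no vertebrate name was 49.0%, 80.2% and 75.0%. Whether foreign reads in the day 0 libraries, counted under shared names, raised the day 0 levels of the fallen miRNAs was not tested. Reads from the source of miR-378, miR-486 and miR-206 are argued against for miR-33-5p and miR-9341, whose ratio to these varied over the 9 later libraries with a chi-square per degree of freedom of 68.7 and 18.0, and are consistent with the rise of the vertebrate form of miR-1, with 1.92 (1.72 among the 3 miRNAs themselves), while another vertebrate source was not tested. A batch as the only cause is argued against by days 2 and 6, between which 22 of 26 called miRNAs had the sign of their day 4 change (limma's rotation test, p = 0.0034, which rests on the model's spread, since an exact permutation of 3 against 3 libraries cannot go below 0.1), though edgeR called 0 single miRNAs there (14 at an unadjusted p under 0.05, with 4 called by DESeq2 and 0 by limma-voom) and miR-193 was too low to be tested. The median change there was 0.64 on the log2 scale, against 2.11 between day 0 and day 4, so a batch may still account for most of the size of the day 0 differences, where it coincides with age and cannot be told apart from it, and age itself stays open.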

How the results depend on the processing

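Of 48 called changes, the 45 chosen by the naming rule and those of the minor form of miR-8-3p at 3 ages, no direction reversed under the alternatives run. All 48 were called with no overlap between the libraries of the 2 ages. Leaving out 1 library could therefore hardly turn a direction, and the lack of reversals is no evidence of robustness. Of 1190 alternative values of these, 1013 kept their side of the threshold and 177 lost the call. For 5 DESeq2 results there was no adjusted p. The fit of only the 6 libraries compared and the fit of summed names each kept 23 and lost 25 of the 48 calls. The cause of the losses was not tested except where fewer libraries or other rows were used by construction. Among the 10 most abundant miRNAs, changes that were not called did turn without day 0 replicate 1: miR-275-3p went from -1.11, -1.04 and -1.06 at days 2, 4 and 6 to 0.16, 0.23 and 0.21, and at day 2 bantam-3p went from 0.30 to -0.17 and miR-14-3p from 0.25 to -0.26. For the test over the 4 ages the title-number replicate block gave 16 miRNAs and all rows as deposited 347. The replicate block by title number also gave 6 higher at day 6 against day 0. Libraries with the same number showed no sign of deviating together (mean correlation -0.05, range -0.69 to 0.33, 6 of 18 pairs above 0.1). With 3 libraries per age, these correlations cannot exclude that the numbers pair the samples. The replicate block by description number gave 3 higher and 8 lower at day 6 against day 2. Day 0 replicate 1 is the only library with its description number. That block therefore gives it a level of its own and in effect leaves it out. Total counts gave 6 higher at day 6 against day 0 and 4 lower at day 6 against day 2. DESeq2 gave 7 higher at day 2 against day 0, 1 lower at day 4 against day 2 and 4 lower at day 6 against day 2. Summed names gave 2 higher and 4 lower at day 2 against day 0.

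Among these alternatives, counts near those of the main fit are not given, so a direction left out does not mean a count of 0. With only the 6 libraries compared there were 2 higher and 2 lower at day 2 against day 0. At day 4 against day 0, 8 of the 15 called were lower, and at day 6 there were 2 higher and 11 lower. That fit gave 2 higher and 2 lower at day 4 against day 2, and 1 higher and 3 lower at day 6 against day 2. All rows, chosen after seeing the data as were the next settings, gave 57 higher and 175 lower at day 2, 98 and 248 at day 4, and 117 and 309 at day 6 against day 0. The first joining step alone gave 19 higher at day 6 against day 0. Arthropod names alone gave 2 higher at day 2 against day 0 and 1 lower at day 6 against day 2, where no filter and leaving out miR-8-3p each gave 1 lower. For the lists, camera with an estimated correlation called 0 at day 4 and 0 at day 6 against day 0, and so it did with day 0 replicate 1 left out, 0 at day 4 and 0 at day 6. The more abundant arm alone gave 1 at day 6 against day 2. Total counts gave 4 at day 4 against day 0 and 1 at day 6 against day 2. Camera with an estimated correlation called 0 at day 6 against day 2, with a lowest adjusted p of 0.358. Total counts for the lists, and camera without that library, were added after seeing the data.

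Leaving out each library in turn gave 17 to 33 miRNAs over the 4 ages. The ranges were 1 to 8 higher and 4 to 20 lower at day 2, 3 to 14 higher and 11 to 23 lower at day 4, and 6 to 15 higher and 14 to 23 lower at day 6 against day 0. They were 0 to 0 higher and 0 to 2 lower at day 4 against day 2, 0 to 0 higher and lower at day 6 against day 4, and 0 to 3 higher and 0 to 6 lower at day 6 against day 2. For the lists only day 0 replicate 1 was left out, which in fry gave 4, 5 and 7 lists at days 2, 4 and 6 against day 0. It gave 1 at day 4 against day 2, 0 at day 6 against day 4 and 1 at day 6 against day 2. Camera with an estimated correlation called 0 lists in each of these comparisons without that library. Its lowest adjusted p was 0.678 at day 4 against day 2 and 0.358 at day 6 against day 2.

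TMM and total counts shifted the median log2 change of all miRNAs from 0 to -0.2 at day 4 and from 0.32 to -0.06 at day 6 against day 0. An alternative without predicted miRNAs was not run, since the table names none, and alternatives for normalized values did not apply to counts.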

Other observations

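The tests on splits in this part were chosen after the counts they bear on were seen. Within day 6, replicate 3 differed from the others in a few miRNAs. miR-33-5p stood at 65.6 CPM there, against 972 and 937, and miR-276-5p at 176, against 1691 and 1569, while miR-14-3p stood at 78559, against 25572 and 20913. miR-281-3p varied within each age, from 57.8 to 1015 CPM at day 0 and from 46.1 to 390 at day 6.

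Of 100 splits of the 12 libraries into 4 groups of 3, only the real split (1 of 100) gave as many as 25 miRNAs. The highest other split gave 16. This argues against chance assignment of the libraries to ages for the test over the 4 ages, if the libraries are independent samples. It does not separate age from a batch that coincides with it. For 3 against 3 libraries there are 10 splits, too few for a share under 0.05. At day 2 against day 0 the real split gave 4 and the highest other 0, a count of 1 split. At day 4 against day 0 these were 15 and 0, with 1 split, and at day 6 against day 0 they were 13 and 0, with 1 split. At day 4 against day 2 and at day 6 against day 2 they were 4 and 0, with 1 split each. At day 6 against day 4 the real split gave 0, as did all 10 splits.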
